A study of Mus musculus with 8 samples.

How the data were processed

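RNA was measured by sequencing in 8 libraries: naive (CD19+Fas-GL7-) and GC (CD19+Fas+GL7+) B cells of miR-217TG mice and littermate controls, 2 libraries per group. Per the labels, cells were sorted from Peyer's patches pooled from 4 to 6 animals per genotype in 2 independent experiments. Each p-value thus rests on a spread between libraries, which joins differences between such pools with noise of amplification and library making. RNA was amplified with the Ovation SPIA system, sheared to 150 to 200 bp, and 200 ng of cDNA was made into libraries without a strand mark, with 10 PCR cycles, for the Genome Analyzer IIx. The authors aligned reads to mm9 with TopHat2 2.0.7 and deposited HTSeq 0.5.3p9 count files, 1 integer read count per gene and library. The gene annotation and the strand setting of the counting were not given in the sources used here. Each file held 23284 genes, taken as in the file, and 5 HTSeq summary lines, which were left out of every test.

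The summary lines put the reads that mapped to more than 1 place at 47.8 to 64.9% of a file's total, those outside genes at 11.7 to 18.8%, and ambiguous ones at 0.28 to 0.42%. File totals ran from 14861992 to 22442469, and gene reads from 22.6 to 33.3% of them; the depth of each library is given with the results. Reads that map to several places were not counted, so genes with near-identical copies (Rps18 among them) are uncertain, and without strand so are genes that overlap an antisense one (Peg13 among them). The table held no immunoglobulin constant region genes and no mitochondrially encoded genes, so these 2 lists had 0 tested members, and Ighd and Muc2 were missing from others.

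Counts were fitted with edgeR 4.0.16 in R 4.3.3 (limma 3.58.1), by quasi-likelihood F tests on group means of all 8 libraries, with TMM factors. Genes were kept by filterByExpr at a minimum count of 10, which left 11291, with 4 residual and 6.1 prior degrees of freedom. Benjamini-Hochberg adjustment ran over all genes of a contrast, with the threshold at 0.05. Contrasts were GC versus naive in each genotype, miR-217TG versus control in GC, in naive and averaged over both, and the interaction. The replicate number was not used as a block, since no label says that it marks an experiment. With 2 libraries per group the spread rests on the other groups too, and a library left alone in a group when its partner was left out was assumed to vary like them.

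Lists fixed in advance covered GC, naive follicular, dark zone, light zone, plasma cell, replication, mitosis, double-strand break, base excision and mismatch repair, cohesin, p53, apoptosis, B cell receptor, class II, glycolysis, interferon and immediate early genes. Others held markers of T cells, of macrophages, monocytes and granulocytes, of intestinal epithelium, of stroma and endothelium and of erythroid cells, and sex-linked transcripts. Lists with at least 5 tested members, 22 in all, were tested with camera at a preset correlation of 0.01 and, as an alternative, an estimated one. The 2 lists of 4 genes tied to miR-217 (repair genes named by the study, and targets known from other tissues) were given by gene. Called members were counted over all genes and adjusted over the list alone.

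Genes were named by a rule. Per contrast these were the 10 largest changes in each direction among called genes whose libraries on 1 side all lay above those on the other and whose mean was at least 5 CPM in a group. Gene models with only a systematic name, antigen receptor segments and pseudogenes were left out. With fewer than 5 called, the 5 smallest p-values were given as not past the threshold. Members of lists with the smallest p and 13 genes of prior interest (Mir217, Aicda, Bcl6, Fas, Nbn, Xrcc2, Lig4, Pds5b, Mre11a, Sirt1, Kras, Ezh2 and Pten) completed it; some list members shown beside them were picked after their values were seen. Folds against a group at 0 reads were set against 3 counts over the group. With 1 to 3 reads, the ratio of pooled CPM was given with its exact binomial 95% interval. Both the folds given as at least a value and these intervals reflect counting alone, not the spread between libraries.

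Seed sites of miR-217 were sought in the longest annotated 3' UTR of 10727 tested genes in GENCODE M21 (GRCm38), used for sequences and transcript lengths alone and matched by symbol, since it is not the authors' annotation. The median log2 difference of genes with and without a site was ranked among the 630 7-mers of the same base composition, the seed match included. Counts of 7-mers as low include the seed match itself. Genes detected at equal depth were computed for 3500000 reads. Raw counts of replicate libraries were checked for a duplicate deposit, and none was found (chi-square over its degrees of freedom 67.2 or more). The code was tested on 1 simulated data set of 10760 genes with 50 genes changed at each fold; the DESeq2 part was added after its calls were seen.

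Alternatives were RLE factors, library totals, no low-count filter, a stricter filter at 5 CPM, a replicate block, a fit on the compared groups only, DESeq2 1.42.0, each library left out in turn and, for sites, 8-mers and the coding sequence. The contrasts, tests, lists, naming rule and these alternatives were fixed before the data were examined. Robust dispersions, voom with sample weights, both naive libraries numbered 1 left out, a block with control GC numbers crossed, and removal of the length trend per library were added later. The fits with fewer libraries first filtered genes again; they were changed to the 11291 genes after those values were seen, and both forms are given. The Reg3 to Fabp ratio was first permuted over both cell types and counted against less epithelial RNA. It was changed to permutation within cell type, and is no longer counted against it, after its value was seen. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 were used for sites, matched lists and figures.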

Results

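B cells were sorted from Peyer's patches, gut lymphoid tissue with standing germinal centres (GC), of mice carrying a miR-217 transgene (miR-217TG) and of littermate controls. Naive (CD19+Fas-GL7-) and GC (CD19+Fas+GL7+) cells of each genotype gave 4 groups of 2 libraries. Values are mean normalised read counts (CPM) ± SD over the 2 libraries of a group, and log2 fold changes ± SE. The SE was derived as the size of the log2 fold change divided by the square root of its F statistic. Reads assigned to genes numbered 3809385 and 5428192 for control naive, 5488797 and 4544568 for control GC, 5306069 and 6159673 for miR-217TG naive, and 4180740 and 5116259 for miR-217TG GC. At an equal depth of 3500000 reads, genes detected numbered 10198 and 12662, 11666 and 12532, 11207 and 13947, and 10577 and 10876 in the same order.

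Reads on Mir217, the gene of the precursor of the transgene's microRNA, were seen in miR-217TG libraries alone. Mir217 had 0 reads in each of the 4 control libraries, 9 and 15 in miR-217TG naive and 25 and 24 in miR-217TG GC B cells. Against a floor of 3 counts over the control group, Mir217 was at least 18.7-fold higher in GC and at least 6.65-fold higher in naive miR-217TG cells (adjusted p = 0.902 and 1.00, not past the threshold). Such bounds, here and below, reflect counting alone, not the spread between libraries. Between miR-217TG cell types Mir217 stood at 5.56 ± 1.43 CPM in GC and 2.07 ± 0.240 CPM in naive cells (log2 fold change 1.41 ± 2.19, adjusted p = 0.781). These reads come from the precursor and do not measure the mature microRNA.

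Replicate libraries of a group correlated at r = 0.81 (control naive), 0.78 (control GC), 0.86 (miR-217TG naive) and 0.78 (miR-217TG GC) on log2 CPM, below the 0.97 between the naive libraries numbered 2 of the 2 genotypes. Principal component 1 held 43.7% of the variance and component 2 held 15.0%. Genes with at least 50 reads in 1 replicate and 0 in the other numbered 275, 182, 129 and 389 in control naive, control GC, miR-217TG naive and miR-217TG GC. Abundance by transcript length differed between libraries: genes in the longest 20% of transcripts deviated from those in the shortest 20% by 0.21 and 1.34 (log2) in control naive, 0.27 and -1.12 in control GC, 0.20 and 1.43 in miR-217TG naive, and -1.10 and -0.90 in miR-217TG GC. The most abundant transcript, Cd74, the class II invariant chain, took between 4.09% and 12.4% of the gene reads of a library. The biological coefficient of variation was 0.83.

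**Figure D1:**
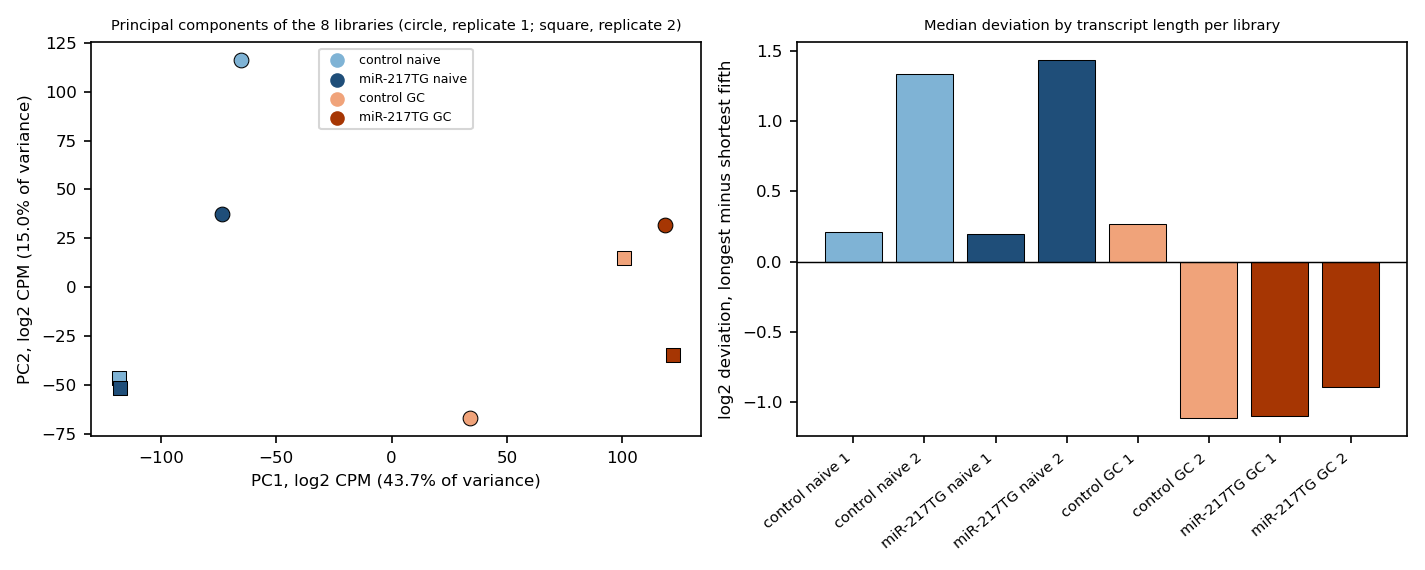
Principal components of log2 CPM of the 8 libraries (left), and the median log2 deviation of genes in the longest 20% of transcripts minus that of the shortest 20% per library (right). Circles, replicate 1; squares, replicate 2.

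In control mice, GC B cells differed from naive B cells by a GC identity programme, by replication and mitosis genes, and by lower naive follicular genes such as the receptors S1pr1 and Ccr7. Gcet2, a GC B cell adaptor, rose from 0.752 ± 0.601 to 968.9 ± 153 CPM (log2 fold change 10.43 ± 0.84, adjusted p = 0.00104). Aicda, which encodes activation-induced deaminase, rose from 2.55 ± 1.94 to 1221 ± 376 CPM (8.82 ± 0.94, adjusted p = 0.00564). S1pr2, a receptor that confines B cells to the GC, rose from 1.34 ± 0.647 to 476.6 ± 110 CPM (8.39 ± 0.67, adjusted p = 0.00104). S1pr1, the egress receptor, fell from 682.5 ± 12 to 18.1 ± 1.29 CPM (-5.23 ± 0.66, adjusted p = 0.00924). Ccr7, a homing receptor, fell from 300.7 ± 81.3 to 4.47 ± 5.84 CPM (-6.09 ± 1.15, adjusted p = 0.0351). Fcer2a (CD23) fell from 1461 ± 32.4 to 178.8 ± 25.1 CPM (-3.03 ± 0.47, adjusted p = 0.0178). Igj, the J chain of secreted antibody, rose from 331.0 ± 5.93 to 2654 ± 924 CPM (3.00 ± 0.51, adjusted p = 0.0245).

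By list, 10 of 15 GC genes rose in control mice (13 adjusted over the list alone), among them Mef2b (5.93 ± 0.70), Rgs13 (5.18 ± 0.72) and Eaf2 (5.20 ± 0.96). Of 13 naive follicular genes 5 fell and all 13 did adjusted over the list alone, with Bcl2, an anti-apoptotic gene (-6.21 ± 1.12), and Gpr183, the EBI2 receptor (-5.20 ± 0.96), beside S1pr1, Ccr7 and Fcer2a. Replication genes rose in 11 of 28 cases (20 adjusted over the list alone), with Tyms (4.90 ± 0.59), Mcm6 (3.95 ± 0.52) and Uhrf1 (5.64 ± 0.80). Mitosis genes rose in 8 of 25 cases (23 adjusted over the list alone), with Cdk1 (6.38 ± 0.91), Cdc20 (5.13 ± 0.77) and Ccnb2 (7.47 ± 1.17). Dark zone genes rose in 3 of 8 cases, namely Aicda, Gcet2 and Ccnb2, all shared with the lists above. Among repair genes, Neil1, a glycosylase (3.92 ± 0.69), and Lig1, a DNA ligase (3.63 ± 0.64), were the 2 of 21 base excision and mismatch repair genes that rose. H2afx, the damage-marked histone (4.11 ± 0.58), was the 1 of 35 double-strand break response genes, and Cdca5, the cohesion factor sororin (7.51 ± 1.19), the 1 of 12 cohesin genes.

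As whole lists in control mice, GC genes (adjusted p = 3.64e-40; 0.00292 with an estimated correlation), replication genes (7.96e-33; 0.00632), mitosis genes (1.02e-34; 0.00386), dark zone genes (4.17e-13; 0.00669) and base excision and mismatch repair genes (7.34e-06; 0.0428) were higher, and naive follicular genes lower (6.32e-22; 0.00386). Class II presentation genes were lower in 11 of 11 cases (adjusted p = 0.000877), such as H2-DMb1 (-1.89 ± 0.48) and Ctss (-1.88 ± 0.46), but adjusted p = 0.347 with an estimated correlation, 0.146 without control naive 1 and 0.106 without control GC 1. Interferon-stimulated genes were lower in 13 of 16 cases (adjusted p = 0.00444), such as Ddx58 (-5.20 ± 1.29), with 0.409 under an estimated correlation, 0.179 without control naive 2 and 0.106 without control GC 1. Double-strand break response genes were higher in 23 of 35 cases (adjusted p = 0.0280), with 0.602 under an estimated correlation, 0.466 without control naive 1 and 0.208 without control GC 1. Apoptosis genes were higher in 12 of 17 cases (adjusted p = 0.0396), such as Bid (1.79 ± 0.53), with 0.347 under an estimated correlation, 0.0744 without control naive 1, 0.0673 without control naive 2 and 0.153 without control GC 2.

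The largest changes past the threshold in control mice were in genes near 0 on 1 side. Kif2c, a mitotic kinesin (at least 216-fold higher), Mxd3, a MAX partner (192), Aif1l, an actin-binding protein (126), Sgol1, which protects centromeric cohesion (112), and Lrrc49, a leucine-rich repeat gene (102), had 0 naive reads. With 1 or 2 naive reads, CPM ratios were 1408 (counting interval 389 to 11630) for Cdca3, a mitotic entry factor, 1023 (183 to 40447) for Sh3bgrl2, an SH3-binding protein, 662 (118 to 26171) for E2f8, a cell cycle repressor, and 560 (155 to 4633) for Bub1b, of the spindle checkpoint. In the other direction, Wls, needed for Wnt secretion (at least 169-fold lower), Gpr65, a proton-sensing receptor (145), Itm2a, a membrane protein (119), and Col6a4, a collagen (101), had 0 GC reads. With 1 or 2 GC reads, ratios were 1006 (278 to 8312) for Cnn3, an actin-binding calponin, and 872 (156 to 34491) for Kctd12, a GABA-B receptor subunit. They were 474 (84.7 to 18781) for Pltp, a phospholipid transfer protein, 468 (83.5 to 18522) for Cobll1, a cordon-bleu relative, 345 (61.5 to 13675) for Tmcc3, a coiled-coil protein, and 298 (82.1 to 2467) for Peg13, a noncoding RNA. Adjusted p-values of these genes lay between 0.00266 for Cdca3 and 0.0485 for Lrrc49.

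In all, 142 of 11291 genes passed in control mice (96 higher and 46 lower in GC; 1331 at an unadjusted p under 0.05). For each gene named as past the threshold both GC libraries lay on the same side of both naive libraries. The count was 17 without control naive 1, 52 without control naive 2, 101 without control GC 1, 32 without control GC 2 and 8 without both naive libraries numbered 1. Of the 38 called list members, 7, 16, 30 and 12 passed in the 4 settings without 1 library, with Gcet2, Aicda, S1pr2 and Mef2b passing without each of the 8 libraries in turn. Of the 21 called genes picked by rule, 4, 10, 9 and 8 passed, and 14 and 17 without miR-217TG naive 1 and 2. Log2 fold changes fell with transcript length (Spearman rho -0.23).

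**Figure D2:**
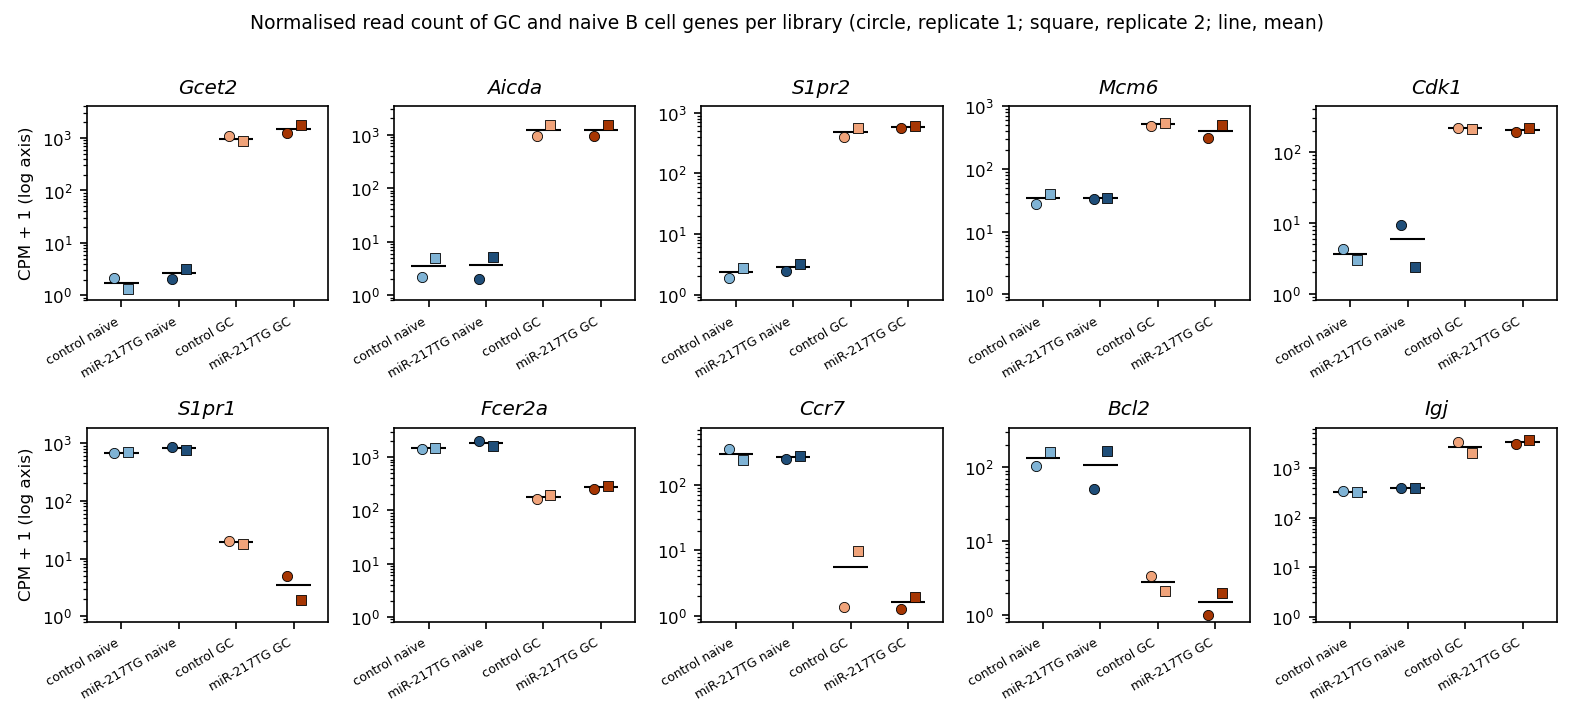
Normalised abundance (CPM + 1) of GC and naive B cell genes in each library of the 4 groups. Circles, replicate 1; squares, replicate 2; lines, group means.

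In miR-217TG mice, GC B cells differed from naive ones in GC identity, naive follicular, replication and mitosis genes too. Gcet2 rose from 1.64 ± 0.836 to 1518 ± 360 CPM (log2 fold change 9.80 ± 0.79, adjusted p = 0.00112), Aicda from 2.61 ± 2.21 to 1227 ± 422 CPM (8.82 ± 0.93, adjusted p = 0.00342) and S1pr2 from 1.86 ± 0.538 to 580.8 ± 33.0 CPM (8.26 ± 0.66, adjusted p = 0.00112). S1pr1 fell from 805.7 ± 67.0 to 2.45 ± 2.12 CPM (-8.40 ± 0.77, adjusted p = 0.00191), and Ccr7 from 264.1 ± 18.5 to 0.605 ± 0.484 CPM (-8.64 ± 1.33, adjusted p = 0.0149). Igj rose from 394.0 ± 6.14 to 3299 ± 361 CPM (3.07 ± 0.51, adjusted p = 0.0185). Fas, used in the sort, changed by 3.91 ± 0.91 (adjusted p = 0.0571) and by 4.44 ± 0.93 in control mice (adjusted p = 0.0544). Bcl6, the GC master regulator, changed by 2.10 ± 0.89 (adjusted p = 0.251) and 1.77 ± 0.88 (adjusted p = 0.479).

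By list, 10 of 15 GC genes rose in miR-217TG mice (13 adjusted over the list alone), the 10 called in control mice. Of 13 naive follicular genes 7 fell (13 adjusted over the list alone), with Ccr6, a chemokine receptor (-5.63 ± 1.17), and Btla, an inhibitory receptor (-4.55 ± 1.00), beyond the 5 of control mice. Replication genes rose in 12 of 28 cases (21 adjusted over the list alone), such as Tyms (4.99 ± 0.59) and Mcm6 (3.62 ± 0.52), and mitosis genes in 9 of 25 (19), such as Cdk1 (5.41 ± 0.86) and Cdc20 (4.49 ± 0.74). Neil1 (4.66 ± 0.72), Lig1 (3.42 ± 0.63), H2afx (4.21 ± 0.58) and Cdca5 (6.67 ± 1.14) rose here too. Wrn, a helicase of the double-strand break list, had 0 reads in miR-217TG GC B cells and fell at least 65.0-fold (adjusted p = 0.0361; 0.116 without miR-217TG naive 1, 0.114 without naive 2, 0.0811 without GC 1 and 0.101 without GC 2 of this genotype, 0.0622 and 0.0521 without control naive 1 and 2). Ccnd2, cyclin D2 of the light zone list, fell from 191.0 ± 36.2 to 30.4 ± 3.15 CPM (-2.65 ± 0.52, adjusted p = 0.0312; 0.102 to 0.163 without 1 of the 4 miR-217TG libraries).

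As whole lists in miR-217TG mice, GC genes (adjusted p = 1.51e-32; 0.00445 with an estimated correlation), replication genes (1.92e-26; 0.00846), mitosis genes (1.46e-22; 0.00846) and dark zone genes (3.42e-09; 0.0208) were higher, and naive follicular genes lower (4.82e-20; 0.00846). Base excision and mismatch repair genes were higher at adjusted p = 8.22e-05 but 0.0665 with an estimated correlation. Interferon-stimulated genes were lower in 13 of 16 cases (adjusted p = 0.00563; 0.455 with an estimated correlation). Markers of other cells moved too: T cell markers were higher in GC cells in 8 of 10 cases (adjusted p = 0.0176; 0.455 with an estimated correlation, 0.104 without miR-217TG GC 2), such as Cd3g at 2.29 ± 0.556 and 26.2 ± 2.74 CPM. Intestinal epithelium markers were higher in 11 of 14 cases (adjusted p = 0.0123; 0.595 with an estimated correlation, 0.261 without miR-217TG naive 2, 0.384 without miR-217TG GC 2), such as Epcam at 2.43 ± 1.33 and 19.3 ± 8.33 CPM.

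Bub1b (at least 519-fold higher), Lrrc32, a TGF-beta docking receptor (123), Gfi1b, a transcriptional repressor (116), and Nuf2, of the kinetochore (95.4), had 0 reads in miR-217TG naive cells. With 2 naive reads each, ratios were 661 (183 to 5468) for Emp2, an epithelial membrane protein, 627 (173 to 5188) for Sh3bgrl2 and 400 (110 to 3310) for Kif2c, and Cdkn3, a CDK phosphatase, rose from 0.689 ± 0.0800 to 221.8 ± 104 CPM (8.27 ± 0.79, adjusted p = 0.00206). The 10 largest falls all had 0 reads in miR-217TG GC cells: Csnk1g3, a casein kinase (at least 273-fold), Mtap, of methionine salvage (262), Peg13 (175), Serpini1, a serpin (174), Cobll1 (165), Stat4, a cytokine signal transducer (162), Gpr65 (135), Hck, a Src family kinase (124), Senp8, a NEDD8 protease (105), and Itih5, a matrix protein (104). Adjusted p-values of these genes lay between 0.00206 for Cdkn3 and 0.0459 for Hck.

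In all, 264 genes passed in miR-217TG mice (115 higher and 149 lower in GC; 2070 at an unadjusted p under 0.05, and 1181 without miR-217TG naive 2). More were higher than lower without control naive 1 (134 and 111), control naive 2 (162 and 118), miR-217TG naive 2 (22 and 19) or miR-217TG GC 2 (47 and 37). The same held with the replicate block (103 and 96), library totals (103 and 99), voom weights (195 and 136) and the length trend removed (182 and 148; 990 and 961 at an unadjusted p under 0.05). Again both GC libraries lay on the same side of both naive libraries for each gene named as past the threshold. The count was 42 and 41 without miR-217TG naive 1 and 2, and 89 and 84 without miR-217TG GC 1 and 2. It was 16 (10 higher and 6 lower) without both naive libraries numbered 1. Of the 45 called list members, 12, 12, 21 and 21 passed in the 4 settings without 1 miR-217TG library, with Gcet2, Aicda, S1pr2, S1pr1 and Tyms among those that passed without each of the 8 libraries. Of the 20 called genes picked by rule, 6, 8, 11 and 10 passed. Log2 fold changes fell with transcript length (Spearman rho -0.31).

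The GC change shared many genes between genotypes. Of the genes that passed, 86 rose in both genotypes and 40 fell in both, with 0 in opposite directions. The contrasts share no library, but their calls are not independent, since 1 fit shared dispersions over all libraries. With each genotype fitted on its own libraries, 79 rose and 41 fell in both. When genes were also filtered again on those libraries, 21 rose and 6 fell in both. Those higher and lower in both were 12 and 5 without control naive 1, 34 and 13 without control naive 2, 64 and 20 without control GC 1, and 25 and 5 without control GC 2. They were 19 and 10 without miR-217TG naive 1, 22 and 12 without naive 2, 38 and 24 without GC 1, and 44 and 16 without GC 2 of that genotype. Log2 fold changes correlated at r = 0.57 over all genes (0.32 without control naive 2) and 0.89 over the 280 genes called in either, of which 279 had the same direction. Shared members included Gcet2, Aicda, S1pr2, Cdk1 and Tyms among those higher, and S1pr1, Ccr7, Bcl2 and Gpr183 among those lower. Of the genes named here, only Gcet2, Aicda and S1pr2 kept their calls in both genotypes without each library in turn.

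The remaining lists did not pass in either genotype. Adjusted p-values in control and miR-217TG mice were 0.365 and 0.553 for light zone genes, 0.191 and 0.274 for plasma cell genes, 0.977 and 0.573 for cohesin genes, 0.932 and 0.668 for p53 targets, 0.187 and 0.311 for B cell receptor signalling, 0.0736 and 0.134 for glycolysis, and 0.222 and 0.975 for immediate early genes. They were 0.977 and 0.0839 for macrophage, monocyte and granulocyte markers, 0.640 and 0.668 for stromal and endothelial markers, and 0.977 and 0.295 for sex-linked transcripts. Of the stromal list Pecam1 fell in miR-217TG mice (-4.25 ± 0.94, adjusted p = 0.0478), a call lost without control naive 1 (0.0649), naive 2 (0.0518) or GC 2 (0.0593), or miR-217TG naive 1 (0.130), naive 2 (0.114) or GC 1 (0.0720). In control mice T cell markers had adjusted p = 0.191 and epithelium markers 0.324; in miR-217TG mice double-strand break genes had 0.305, apoptosis genes 0.346 and class II genes 0.134. The erythroid list had 1 tested member, Alas2 (0.20 ± 2.29 and -0.68 ± 2.30). Of the genes of prior interest, Ezh2, a histone methyltransferase (3.22 ± 1.54 and 3.33 ± 1.55), Kras, a GTPase (-2.60 ± 1.20 and -2.76 ± 1.22), Sirt1, a deacetylase (-2.19 ± 0.93 and -0.57 ± 0.89), Pten, a lipid phosphatase (-0.34 ± 1.11 and -1.03 ± 1.12), and Mre11a, the MRN nuclease (-0.15 ± 1.02 and -0.39 ± 1.02), did not pass.

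In GC B cells, the 4 repair genes that the study links to miR-217 were lower in miR-217TG than in control libraries. Nbn, of the MRN complex that binds broken DNA ends, stood at 21.4 ± 4.08 CPM in control and 1.78 ± 1.77 CPM in miR-217TG (log2 fold change -3.55 ± 1.31, adjusted p = 0.873). Pds5b, a cohesin-associated factor, stood at 34.8 ± 6.78 and 3.61 ± 2.13 CPM (-3.25 ± 1.18, adjusted p = 0.864). Lig4, the ligase of end joining, had 28.5 ± 23.4 and 0.263 ± 0.372 CPM, or 319 and 2 reads (ratio 139, counting interval 38.2 to 1153; adjusted p = 0.791). Xrcc2, a RAD51 paralog, had 73 and 13 reads in the control and 0 in both miR-217TG libraries (at least 25-fold lower, adjusted p = 0.873). Each was lower in 2 of 2 miR-217TG libraries than in 2 of 2 controls; 0 of 4 passed over all genes and 4 of 4 adjusted over the list alone. Over the alternatives their adjusted p ran from 0.0289 (Lig4 by DESeq2) to 1.00. The list was not independent evidence, since the study itself named these genes. The miR-217TG GC libraries detected fewer genes at equal depth (10577 and 10876 against 11666 and 12532 in control GC). Genes with at least 50 reads in 1 replicate and 0 in the other were most numerous in miR-217TG GC (389, against 182 in control GC). With the length trend removed the log2 differences were -3.47 for Nbn, -2.71 for Pds5b, -6.17 for Lig4 and -8.29 for Xrcc2, against -3.55, -3.25, -6.74 and -8.28 before, and 0 of 4 passed (adjusted p from 0.758 to 0.894). Their naive differences were 0.62 ± 1.17, 0.39 ± 1.07, 0.14 ± 1.63 and 0.90 ± 2.03 (adjusted p = 1.00 each).

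**Figure D3:**
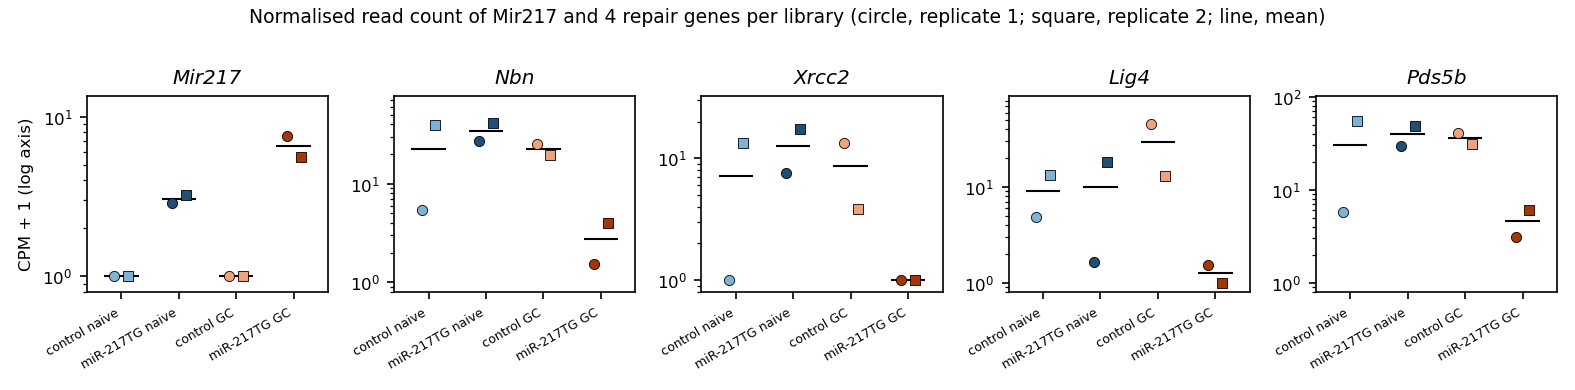
Normalised abundance (CPM + 1) of Mir217 and of the 4 repair genes linked to miR-217 by the study in each library of the 4 groups. Circles, replicate 1; squares, replicate 2; lines, group means.

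GC identity genes did not pass between genotypes, with differences of 0.65 ± 0.53 for Gcet2, 0.29 ± 0.47 for S1pr2, -0.09 ± 0.85 for Bcl6 and 0.12 ± 0.81 for Fas, and with Aicda at 1221 ± 376 and 1227 ± 422 CPM. The smallest p-values between GC groups, none past the threshold (adjusted p = 0.589 each), belonged to Abca1, a cholesterol exporter (101 control and 3 miR-217TG reads; ratio 29.4, 9.76 to 145), Mcfd2, a cargo receptor cofactor (427 and 3; 124, 42.2 to 604), and Ddx10, an RNA helicase (295 and 2; 129, 35.3 to 1067). Mtap (at least 20.6-fold lower) and Kdm1b, a histone demethylase (at least 33.4-fold lower), had 0 reads in miR-217TG GC cells. DESeq2 gave adjusted p = 0.00383, 4.64e-05 and 0.000531 for Abca1, Mcfd2 and Ddx10, and edgeR with no low-count filter 0.00109, 0.000134 and 0.000134, while the replicate block gave 0.862 for each and the range over all alternatives reached 1.00. Wrn had 0 reads in miR-217TG GC cells (at least 27.0-fold lower, adjusted p = 0.595), and Mre11a differed by -0.18 ± 1.02. The miR-217 targets known from other tissues, Sirt1 (0.69 ± 0.90), Kras (-0.22 ± 1.15), Ezh2 (-0.47 ± 1.41) and Pten (-0.47 ± 1.11), had 0 of 4 called over all genes.

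By list, naive follicular genes were lower in miR-217TG GC cells in 10 of 13 cases (adjusted p = 0.0458), such as S1pr1 at 18.1 ± 1.29 and 2.45 ± 2.12 CPM (-2.92 ± 0.64) and Ccr7 (-2.74 ± 1.18). The call was lost with an estimated correlation (adjusted p = 0.707), with the replicate block (0.0600), and without control naive 1 (0.0545), control GC 2 (0.387) or miR-217TG GC 2 (0.269). Macrophage, monocyte and granulocyte markers were higher in 8 of 10 cases (adjusted p = 0.0458; 0.946 with an estimated correlation), such as Lyz2, lysozyme, at 35 ± 17 and 110.3 ± 0.112 CPM. That call was lost with the replicate block (0.0600), and without control naive 1 (0.0545), control GC 1 (0.238), control GC 2 (0.119), miR-217TG GC 1 (0.194) or miR-217TG GC 2 (0.202). Of the other lists, cohesin genes such as Smc3, a ring subunit (log2 fold change -3.87), and class II genes (adjusted p = 0.183 each) came nearest, followed by immediate early genes (0.382), and the rest had adjusted p from 0.708 (apoptosis) to 0.997 (p53 targets), with GC genes and double-strand break genes at 0.838 each.

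By edgeR 0 genes passed between GC groups, with 602 at an unadjusted p under 0.05 (86 higher and 516 lower in miR-217TG; 564.55 expected). The skew rested on 1 library: without control GC 1 the split was 308 higher and 330 lower. The higher count was 57 without miR-217TG naive 1 and 132 without miR-217TG GC 1. The number fell below that expected in the fit on the compared groups only (339; 62 higher and 277 lower) and without both naive libraries numbered 1 (385; 44 and 341). DESeq2 called 137 (12 higher and 125 lower, Lig4 among them at adjusted p = 0.0289) and edgeR with no low-count filter 107 (6 and 101). In 1 simulated data set at this size, edgeR recovered 0, 1, 18 and 39 of the 50 genes changed 2, 4, 16 and 64-fold, with 2 false calls, and DESeq2 recovered 3, 11, 31 and 43 with 75 false calls, and made 47 calls in the unchanged naive contrast where edgeR made 0. The spread in that simulation came from edgeR's own estimates, which favours edgeR. The simulated naive contrast was also unlike the real one, where DESeq2 made no calls. Its false calls in the simulation therefore do not show how many of the 137 are false. Both miR-217TG GC libraries detected fewer genes at equal depth than both control GC libraries, and differences fell with transcript length (Spearman rho -0.18).

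In naive B cells, no list member passed between genotypes, and 4 list calls held only at the preset correlation. Reg3b and Reg3g, antimicrobial lectins of the gut lining, stood at 89.4 ± 90.3 and 63.9 ± 76.8 CPM in control and 7.89 ± 8.21 and 8.46 ± 10.7 CPM in miR-217TG naive cells. Epithelium markers were lower in 14 of 14 cases (adjusted p = 1.53e-08), but adjusted p = 0.600 with an estimated correlation, 0.263 without control naive 1 and 0.193 without miR-217TG naive 2. Mitosis genes were higher in 16 of 25 cases (adjusted p = 0.00910; 0.600 with an estimated correlation, 0.102 without control naive 2, 0.135 without miR-217TG naive 1), with Aurka, a spindle kinase, at 2.37 ± 3.35 and 11.8 ± 1.14 CPM. Dark zone genes were higher in 7 of 8 cases (adjusted p = 0.00676; 0.526 with an estimated correlation, 0.102 without control naive 2, 0.0707 without miR-217TG naive 2), with Aurka and Bub1, a checkpoint kinase at 0 and 4.86 ± 6.24 CPM, in both lists. T cell markers were lower in 9 of 10 cases (adjusted p = 0.00910; 0.792 with an estimated correlation, 0.858 without control naive 2, 0.193 without miR-217TG naive 2), such as Cd3e at 9.90 ± 8.18 and 2.72 ± 0.575 CPM.

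The smallest p-values between naive groups, none past the threshold (adjusted p = 1.00 each), belonged to Cdca3 (2 control and 38 miR-217TG reads; ratio 15.8, 4.08 to 135), Nuf2 (0 miR-217TG reads, at least 8.42-fold lower), Lrrc49 and Mxd3 (0 control reads, at least 21.6-fold and 4.71-fold higher) and Trim12a, a TRIM family gene (0 miR-217TG reads, at least 149-fold lower). The folds of these genes bound counting error alone, and the spread between libraries leaves them open. Naive differences of Bcl6 (-0.43 ± 0.86), Fas (0.64 ± 0.82), Mre11a (0.07 ± 1.02), Sirt1 (-0.93 ± 0.90), Kras (-0.06 ± 1.13), Ezh2 (-0.58 ± 1.45) and Pten (0.22 ± 1.11) did not pass. By edgeR 0 genes passed, with 56 at an unadjusted p under 0.05 (21 higher and 35 lower) against 564.55 expected. That number was 396 without control naive 2 (320 higher and 76 lower), 147 without miR-217TG naive 2, 31 without control naive 1 (19 higher and 12 lower) and 33 without miR-217TG naive 1. It was 33 with the replicate block and 18 without both naive libraries numbered 1. DESeq2 called 0 genes and edgeR with no low-count filter 2.

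Whether the GC change itself differed between genotypes was tested as an interaction. Nbn (-4.17 ± 1.74) and Pds5b (-3.64 ± 1.57) had lower GC-versus-naive differences in miR-217TG than in control cells, and with Xrcc2 and Lig4 made 0 of 4 over all genes (adjusted p = 1.00 each) and 4 of 4 adjusted over the list alone. The study itself named these 4 genes, and the interaction uses the same GC libraries, so the list was not independent evidence here either. In miR-217TG cells Nbn went from 33.0 ± 9.67 CPM in naive to 1.78 ± 1.77 CPM in GC (-4.17 ± 1.35, adjusted p = 0.142), and in control cells from 21.3 ± 23.9 to 21.4 ± 4.08 CPM. S1pr1 (-3.16 ± 0.83), Ccr7 (-2.55 ± 1.48) and Ccnd2 (-1.51 ± 0.69) did not pass, nor did Bcl6 (0.34 ± 1.21), Fas (-0.53 ± 1.15), Mre11a (-0.24 ± 1.44), Sirt1 (1.62 ± 1.27), Kras (-0.17 ± 1.61), Ezh2 (0.11 ± 1.97) or Pten (-0.69 ± 1.57). The smallest p-values belonged to Abca1 (-4.75 ± 0.96), Mcfd2, Csnk1g3, Ddx10 and Senp8, none past the threshold (adjusted p = 1.00 each). By edgeR 0 genes passed, with 358 at an unadjusted p under 0.05 (63 higher and 295 lower), DESeq2 called 12 and edgeR with no low-count filter 24. Without control GC 1 the split was 185 higher and 186 lower. The number was 166 without control naive 1, 595 without control naive 2, 237 without miR-217TG naive 1, 689 without miR-217TG GC 1, 572 without miR-217TG GC 2 and 81 without both naive libraries numbered 1. Of 22 lists 0 passed, the nearest being macrophage (adjusted p = 0.0520), epithelium (0.0637) and naive follicular genes (0.0638). With a replicate block, 2 lists passed, macrophage at 0.0335 and epithelium at 0.0495. With an estimated correlation and no block 0 passed (0.791 for each of these).

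Averaged over the 2 cell types, Fjx1, a homolog of fly four-jointed, and Rps18, a ribosomal protein gene, had the smallest p-values between genotypes. Fjx1 stood at 95.1 ± 38.7 and 78.2 ± 32.4 CPM in miR-217TG naive and GC cells and at 2.20 ± 3.12 and 0.425 ± 0.601 CPM in controls (6.43 ± 1.18). Rps18 differed by -5.05 ± 0.86. Mtap, Abca1 and Ddx10, at 0 to 3 reads in miR-217TG GC cells, followed, and none of the 5 passed the threshold (adjusted p = 1.00 each). Nbn (-1.46 ± 0.85), Pds5b (-1.43 ± 0.78), Xrcc2 and Lig4 had adjusted p = 1.00 too. So did Bcl6 (-0.26 ± 0.60), Fas (0.38 ± 0.58), Mre11a (-0.06 ± 0.72), Sirt1 (-0.12 ± 0.63), Kras (-0.14 ± 0.81), Ezh2 (-0.53 ± 1.01) and Pten (-0.13 ± 0.78). By edgeR 0 genes passed, with 372 at an unadjusted p under 0.05 (62 higher and 310 lower), DESeq2 called 16 and edgeR with no low-count filter 23. The skew turned without control naive 2 (257 higher and 234 lower) or control GC 1 (244 and 219). The number was 145 without miR-217TG naive 1, 722 without miR-217TG GC 1, 608 without miR-217TG GC 2 and 95 without both naive libraries numbered 1. Epithelium markers were lower (adjusted p = 0.00386; 0.933 with an estimated correlation), a call lost without control naive 1 (0.325), control GC 2 (0.119), miR-217TG naive 2 (0.162) or miR-217TG GC 1 (0.490). Dark zone genes were higher (adjusted p = 0.0451; 0.663 with an estimated correlation), a call lost without control naive 2 (0.0785), control GC 2 (0.254), miR-217TG naive 2 (0.0555), miR-217TG GC 1 (0.0528) or miR-217TG GC 2 (0.279).

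Genes with a miR-217 seed match (ATGCAGT, positions 2 to 8) in the 3' UTR did not rank apart from those with other 7-mers in the fit on all libraries. In GC cells 1342 genes with a site had a median log2 difference of -0.17 and 9385 without one -0.07. Of the 630 7-mers of this composition, the seed match included, 361 gave a difference as low. Without control GC 1 the sign changed (difference 0.25, 528 of 630 as low), and without control GC 2 it was -0.38 (92 of 630 as low); without miR-217TG GC 1, 198 were as low. In naive cells 112 of 630 were as low (difference 0.01). The sign turned without control naive 1 (-0.14, 89 as low) and miR-217TG naive 2 (-0.17, 242), and 469 were as low without control naive 2 and 561 without miR-217TG naive 1. With the replicate block 337 were as low, for 8-mers 409, in the coding sequence 326, and 299 without both naive libraries numbered 1. Averaged over cell types 223 of 630 were as low (difference -0.05). The sign turned without control naive 2 (0.09, 384 as low), control GC 1 (0.17, 549) and miR-217TG naive 1 (0.03, 401), and 95 were as low without control GC 2, 339 without control naive 1 and 422 without miR-217TG GC 2. Without both naive libraries numbered 1, 370 were as low, for 8-mers 349 and in the coding sequence 514. The 337 genes with an 8-mer match (ATGCAGTA) gave 252 of 630 in GC cells, and as a list had a camera p of 0.956. Nbn, Xrcc2, Lig4, Pten, Bcl6, Aicda and Fas had 0 ATGCAGT sites in their longest annotated 3' UTR. Pds5b, Mre11a and Sirt1 had 1, Ezh2 had 2 and Kras had 3. Seed matches without this 7-mer were not sought, and the 3' UTR searched for Nbn held 128 bases.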

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

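No test in this part was chosen after the results were seen. No result met the 3 rules set for a closer look. Groups of 2 libraries were too small for the outlier test, the interaction of genotype and cell type had 0 genes past the threshold by edgeR (358 at an unadjusted p under 0.05, from 166 without control naive 1 to 689 without miR-217TG GC 1; 12 by DESeq2), and every deposited count column was used in the comparisons.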

How the results depend on the processing

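Voom with sample weights, robust dispersions, the crossed block, both naive libraries numbered 1 left out, the length correction and the fits that filtered genes again were chosen after the data were seen. Counts are those for GC versus naive in control (142 genes, 10 lists) and in miR-217TG (264, 9), miR-217TG versus control in GC (0, 2), in naive (0, 4) and averaged (0, 2), and the interaction (0, 0).

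With no low-count filter 510 genes passed in control and 1130 in miR-217TG for GC versus naive, 107 between GC groups, 2 between naive groups, 24 for the interaction and 23 averaged; 2 naive, 2 interaction and 1 averaged lists passed. DESeq2 called 717, 1443 and 137 for the first 3 of these, 12 for the interaction and 16 averaged. Voom with sample weights gave 72 in control. The fit on the compared groups only gave 490 in miR-217TG, and 34 in control when genes were filtered again.

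Library totals gave 2 interaction lists and 1 averaged list, RLE factors 0 lists between GC groups and the stricter filter 1. The replicate block gave 0 lists between GC groups and 2 for the interaction. Deviations of libraries with the same number correlated at 0.43 between the naive groups but at -0.19 between control naive and control GC and -0.20 between control GC and miR-217TG naive, so the numbers were not taken to pair libraries. Reads of the Y-linked Ddx3y and Uty followed the numbers in control mice but not in miR-217TG mice, so a pairing stays possible. With control GC numbers crossed, against those reads, the block gave 287 genes in control. An estimated correlation left 6 lists in control and 5 in miR-217TG for GC versus naive, and 0 between GC groups, 0 between naive groups and 0 averaged. With the length trend removed, 0 lists passed between GC groups and 1 averaged.

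Over leave-one-out fits, including those that filtered genes again or left out both naive libraries numbered 1, GC versus naive counts ran from 8 to 260 in control and from 16 to 597 in miR-217TG, and averaged counts from 0 to 1. Both lowest values came without the 2 naive libraries numbered 1. With the same 11291 genes and 1 library left out they ran from 17 to 156 and from 41 to 363. Lists ran from 0 to 3 between GC groups, 1 to 10 between naive groups, 0 to 8 for the interaction and 0 to 9 averaged.

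Of the other values, named genes lost their call in 256 cases and gained one in 67. They stayed as they were in 3457, among them genes called in neither fit, which had no call to lose. The 256 losses fell on 36 results, where 21 named genes were called in control and 20 in miR-217TG for GC versus naive. List calls were lost in 128 cases and kept in 547. No call changed direction.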

Other observations

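The tests of captured transcripts, the share of genes with a site and the Reg3 to Fabp ratio were chosen after the results were seen. So were the tests of G and C content, the separation of all libraries, the splits, the sex-linked reads and the length correction. The seed rank was fixed before the data were examined. The length tests, of genes lower in miR-217TG GC cells and of the naive libraries numbered 2, were not. They address patterns seen in the results, with outcomes set before each test was run. A small set of genes parted the genotypes in both cell types, and other splits of the libraries gave as many. Fjx1 lay at 86.6 ± 30.7 CPM (SD over 4 libraries) in miR-217TG and 1.32 ± 2.10 CPM in control libraries. Trim12a lay at 0 and 20.8 ± 26.6 CPM, and Rps18 at 4.09 ± 2.73 and 140.8 ± 149.8 CPM. The 4 libraries of a genotype span 2 cell types sorted from pools of 2 experiments, so they need not be independent. All 4 miR-217TG libraries lay on 1 side of all 4 controls in 100 of 11291 genes (43 higher and 57 lower). Of 18 splits within cell type 8 gave as many, the real one among them, and the others had a median of 88 and a range of 54 to 629.

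Sex-linked transcripts of the mice differed between pools of the same group. Reads of Ddx3y, a Y-linked helicase, were 84 and 0 in control naive, 536 and 0 in control GC, 60 and 1160 in miR-217TG naive, and 95 and 0 in miR-217TG GC. Xist, the X inactivation RNA, had 50 and 1728, 152 and 117, 0 and 597, and 0 and 51 in the same order. Uty, also Y-linked, had 88 and 0, 305 and 0, 11 and 123, and 2 and 0. In control mice both libraries numbered 1 had reads of Ddx3y and Uty, and both numbered 2 had 0. In miR-217TG mice the naive library numbered 2 had the most, and the GC library numbered 2 had 0. The labels do not give the sex of the pooled animals. As a list these transcripts did not pass between genotypes in GC cells (camera, adjusted p = 0.884). The list joins Xist with Y-linked transcripts, which a difference in sex would move in opposite directions. That test therefore cannot show that the sexes were balanced.

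Genes lower in miR-217TG GC cells made up 85.7% (516) of the 602 with an unadjusted p under 0.05 between GC groups, but 51.7% (330 of 638) without control GC 1, so 1 library carries the skew. The highest miR-217TG GC library detected 10876 genes at equal depth against 11666 and 12532 in control GC, as fewer captured transcripts would give, although control GC 2, against which the skew was small, detected the most. The lower genes were long, with a median of 4167 bases against 3440 (3245 to 3641) in 1000 lists matched on expression (percentile 100; 91.1 without control GC 1, 100 without each of the other 3 GC libraries), as a loss of long transcripts would give, and the share fell to 69.4% once the length trend was removed. Repression through seed sites cannot be told apart from its absence. The seed rank stood at percentile 57.3, the outcome set against repression, but moved from 14.6 without control GC 2 to 83.8 without control GC 1. No fit reached the outcome set for repression. The rank did not keep to the outcome set against it without each GC library, a condition that was not part of that outcome as set. The share of genes with a site stood at percentile 30.4 (5.40 without control GC 2, 73.5 without miR-217TG GC 1). Fewer captured transcripts, a loss of long ones, in part or as the whole, and, both not tested, a bias by base composition and an effect of the transgene without sites stay open.

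The naive libraries numbered 2 of the 2 genotypes were more alike (r = 0.97) than either was to its replicate (0.81 and 0.86). Malat1, a nuclear noncoding RNA, stood at 7532 and 6023 CPM in these libraries and at 1201 CPM or less in the other 6. Their ratio to the libraries numbered 1 rose with transcript length (Spearman rho 0.249 in the lower and 0.320 in the other genotype), as a loss of long transcripts in those numbered 1 would give, and fell with the G and C content of transcripts (-0.434 in control and -0.355 in miR-217TG), as a bias by base composition would give. With the other held constant, rho was 0.150 and 0.248 for length and -0.392 and -0.294 for G and C content in control and miR-217TG. The libraries numbered 1 also detected fewer genes at equal depth, 11207 at most against 12662 and 13947; all 3 explanations stay open, and no biological one was tested.

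Epithelium markers were lower in miR-217TG naive cells at the preset correlation alone (adjusted p = 1.53e-08; 0.600 with an estimated correlation, 0.263 without control naive 1 and 0.193 without miR-217TG naive 2). The ratio of Reg3b and Reg3g to Fabp1 and Fabp2 reads was 0.340 ± 0.138 (SD over 4 libraries) in control and 0.0585 ± 0.0246 in miR-217TG, with 0.200 the lowest control and 0.0869 the highest miR-217TG value. This was the outcome set against less epithelial RNA, but the exact p within cell type was 0.0556, the smallest that 36 permutations can give (0.0286 over 70 across cell types, the form run first), and the 4 libraries of a genotype come from pools of 2 experiments. The ratio also rests on Reg3b and Reg3g, the genes that prompted it, so less epithelial RNA in the miR-217TG libraries cannot be told apart from a difference in Reg3 expression between pools. Reads of Fabp1 and Fabp2, absorptive cell transcripts that a CD19 sort should remove, were 1741 and 1074 in control naive and 1623 and 694 in miR-217TG naive libraries. In GC libraries they were 2783 and 2730 in control and 1248 and 5159 in miR-217TG, so the genotypes did not order alike.

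For miR-217TG versus control averaged over cell types, 12 of the 18 splits within cell type gave at least the 372 genes at an unadjusted p under 0.05 of the real split, with 2023 in the highest other; the 372 became 145 without miR-217TG naive 1, 722 without miR-217TG GC 1, 608 without miR-217TG GC 2 and 95 without both naive libraries numbered 1. With 18 splits no share under 0.05 can be reached. Splits with several times more genes point to a structure of the samples, and the 3 highest keep the naive libraries numbered 2 together. With a replicate block 300 genes had an unadjusted p under 0.05 and 0 passed the threshold.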
